A study of Homo sapiens with 16 samples.

How the data were processed

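Poly(A) RNA of the Ewing sarcoma cell line A673 and of 3 monoclonal knockout derivatives of it was sequenced after 48 h with SP-2509 at 500 nM or with its solvent DMSO at 0.1%. The knockouts target MRPL45, CYC1 and UQCRFS1. Per the labels, each of the 8 combinations of line and treatment has 2 replicate libraries, which gives 16 libraries. No label says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, RNA was extracted with a column kit and treated with DNase, and libraries followed standard Illumina protocols. Strand specificity, gene annotation and counting program are not given in the sources used here. Per the submitters' processing notes, the tools were FastQC, MultiQC, Trim Galore, STAR 2.5.2b and DESeq2, and the genome build was hg19, with no roles or order stated.

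The 10 processed tables each hold 39249 genes for 1 comparison of the authors. Each table gives raw counts of the libraries compared, which the authors deposited as whole numbers, per the file headers. The columns that the authors deposited with the prefix norm are a score: the raw counts divided by 1 size factor per library and rounded, as a check of their ratio to the raw counts showed. The authors' deposited log2 fold changes and p-values, unadjusted and adjusted, were used only to count the authors' own calls. A library that appears in several tables had identical counts in each of them. Rows without a gene symbol held between 2.405% and 8.588% of the counts of a library. They carry Ensembl identifiers and stayed in the library totals and the tests. Gene symbols were taken from the tables. MRPL45 is not reported here, because no row used here carries that symbol. Chromosome and transcript GC content were looked up by Ensembl identifier in GENCODE 29, which is on another build than hg19, so no coordinates are given. Of the identifiers, 36551 (93.1%) were also in its table of names.

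Differential expression was computed from the raw counts with edgeR 4.0.16 in R 4.3.3. All 16 libraries entered 1 fit with a mean for each of the 8 groups, TMM normalization, the filterByExpr filter by group and robust quasi-likelihood dispersions. The filter left 21633 genes, the fit had 8 residual degrees of freedom, and the biological coefficient of variation was 0.0716. The quasi-likelihood F-test is two-sided, and p-values were adjusted by the Benjamini-Hochberg method within a comparison. A gene is called where its adjusted p is under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. The 10 comparisons were SP-2509 against DMSO in each of the 4 lines, each knockout line against A673 with DMSO, and for each knockout line the difference between its response to SP-2509 and that of A673. CPM values use TMM-scaled library sizes. The principal components used log2 CPM of 2000 genes with a prior count of 2. Correlations of fold changes across genes used 10597 genes with a mean of at least 5 CPM. The fit was tested on simulated data drawn from the means of the real libraries. For SP-2509 in A673, edgeR recovered 90% of genes changed 1.5-fold, 100% of those changed 2-fold or 3-fold and 98% of those changed 4-fold, with 50 genes per size among 20445. For the difference between the MRPL45 knockout line and A673 these shares were 68%, 100%, 100% and 98%. The changed genes had a mean of at least 5 CPM, as many were raised as lowered, and libraries were drawn independently. So these shares do not speak for genes of lower counts, for changes in most genes or for linked replicates.

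For 34 gene lists, camera of limma 3.58.1 compared the members with all other tested genes at a preset correlation of 0.01, with adjustment over the lists within a comparison. The camera test was repeated with an estimated correlation, and fry tested whether members moved on balance in 1 direction. Counts of called members are given over all tested genes and adjusted over the list alone. Results are given for 23 of the 34 gene lists. The size of the response shared by the lines was measured on genes called in the same direction in the other 2 knockout lines, with fry on the difference between line and A673. Genes with 0 counts in a group were given a bound from a floor of 3 counts over the group, and those with 1 to 3 counts a ratio with a 95% interval. These bounds and intervals cover counting error only. For comparisons against the same A673 libraries, unchanged groups were simulated in 10 draws. Chromosome medians of fold changes were set against 1000 shuffles of the genes.

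The genes named were chosen by a rule. CYC1, UQCRFS1, KDM1A, EWSR1 and FLI1 are always named. For SP-2509 in A673 the rule takes the 10 rising and 10 falling called genes with the largest fold change that reach 5 CPM in the higher group and whose libraries do not overlap between groups. For the other comparisons it takes up to 6 in each direction, without the condition on overlap for the differences in response. Clone-based symbols, pseudogenes and antisense RNAs were passed over. For each list it takes up to 4 called members with the smallest p. Some genes that the rule takes are not reported here. The groups, the comparisons, the tests, the gene lists, this rule and the alternatives, except the pair given last, were fixed before the data were examined.

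The alternatives were DESeq2 size factors and upper-quartile factors, no filter and a stricter filter of 1 CPM in 2 libraries with a total count of 50, the Wald test of DESeq2 1.42.0, a fit to only the libraries compared, a threshold of 2-fold, the replicate number as a block, and leaving out each library in turn. A further pair of alternatives, all libraries thinned to the smallest total and the estimated correlation combined with the block, was chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The authors' comparisons of knockout lines with SP-2509 against A673 with DMSO change line and treatment together and were only counted. A673 clones without a knockout are not analysed here.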

Results

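Poly(A) RNA was sequenced from A673, a cell line of Ewing sarcoma whose growth is driven by the fusion of EWSR1 with FLI1, and from 3 monoclonal derivatives in which MRPL45, CYC1 or UQCRFS1 had been knocked out. MRPL45 is a protein of the large mitochondrial ribosomal subunit, and CYC1 and UQCRFS1 are subunits of respiratory complex III. Each line was treated for 48 h with 500 nM SP-2509, an inhibitor of the histone demethylase LSD1 (gene KDM1A), or with 0.1% DMSO. There were 2 libraries for each of the 8 combinations, and their total counts ranged from 24873597 to 56171036. The MRPL45 knockout line held the smallest totals, with 47074045 and 27544362 counts for its DMSO libraries and 24873597 and 48476073 for its SP-2509 libraries. Totals were 43846845 and 37877638 (DMSO) and 52723845 and 56171036 (SP-2509) in A673, and 46064569 and 43813692 (DMSO) and 51467227 and 49590354 (SP-2509) in the CYC1 knockout line. In the UQCRFS1 knockout line they were 49130355 and 50238095 (DMSO) and 55411378 and 55097368 (SP-2509). No replicate pair agreed within sampling noise, with a chi-square per degree of freedom of 23.19 or more. The first principal component held 53.8% of the variance and set the MRPL45 knockout libraries apart from the other lines. The first also rose with SP-2509 in every line. It went from -44.15 and -44.14 to -0.18 and -0.43 in A673. In the UQCRFS1 knockout line it went from -50.81 and -50.76 to -19.53 and -20.25. In the CYC1 knockout line it went from -36.02 and -36.82 to -20.1 and -17.66. The MRPL45 knockout libraries stood at 81.14 and 80.89 with DMSO and at 90 and 88.8 with SP-2509. The second component held 20.7% and also rose with SP-2509 in every line.

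**Figure D1:**
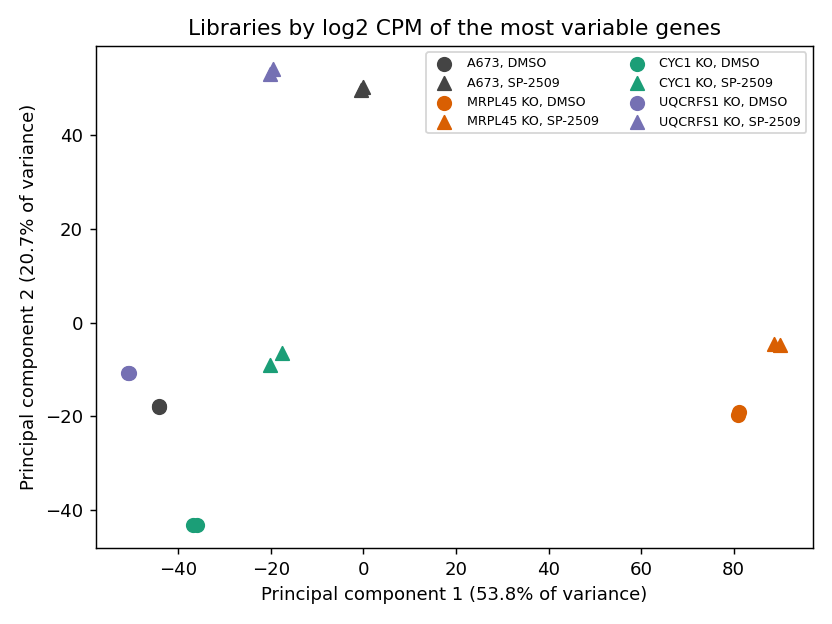
Position of the 16 libraries on the first principal component (53.8% of the variance, horizontal axis) and the second (20.7%, vertical axis) of log2 CPM, with a point for each library, coloured by line and shaped by treatment. The replicates of each group lie close together, and the step from DMSO to SP-2509 is longest in A673 and the UQCRFS1 knockout line.

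The targeted genes came first, since they check the labels. CYC1 (ENSG00000179091) stood at 71.1 and 74.4 CPM in the DMSO libraries of the CYC1 knockout line and at 78.9 and 82.2 CPM in its SP-2509 libraries, against 258.5 to 307.9 CPM in the other 12 libraries. It was 3.92-fold lower than in A673 with DMSO (log2 fold change -1.97 ± 0.07 SE, n = 2 libraries per group; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.34e-16). UQCRFS1 (ENSG00000169021) stood at 58.6 and 60.9 CPM in the DMSO libraries of its own knockout line and at 88.2 and 77.8 CPM with SP-2509, against 88.6 to 118.7 CPM in the other 12 libraries. Its level was 1.68-fold lower than in A673 (-0.74 ± 0.06, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.47e-09) and rose with SP-2509 inside that line (0.47 ± 0.06, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.66e-07). Transcript levels do not show how much protein was left. The label of the MRPL45 knockout line has no such check here.

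KDM1A (ENSG00000004487), which encodes the target of SP-2509, did not pass the test with SP-2509 in any of the 4 lines. Its log2 fold changes were 0.08 ± 0.06 in A673, -0.02 ± 0.06 in the MRPL45 knockout line, 0.02 ± 0.06 in the CYC1 knockout line and 0.01 ± 0.06 in the UQCRFS1 knockout line, where it passed the test at -0.12 with upper-quartile factors. With DMSO it was lower than in A673 in the MRPL45 knockout line (-0.94 ± 0.06, 171 and 174.5 CPM against 321.4 and 342.6) and in the CYC1 knockout line (-0.57 ± 0.06, 225.2 and 222 CPM), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 4.47e-13 and 1.19e-08. EWSR1 (ENSG00000182944) was also lower in the MRPL45 knockout line (-0.53 ± 0.06, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.56e-08). The reads of the fusion transcript fall on EWSR1 and FLI1 (ENSG00000151702) and are not separated from the unfused genes in these counts. FLI1 stood at -0.27 ± 0.06 in the MRPL45 knockout line against A673 with DMSO and at 0.28 ± 0.06 with SP-2509 in A673, the latter 0.10 with upper-quartile factors.

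What SP-2509 does to the transcriptome of A673 was the first question of the design. The genes that rose most included ANKRD1, a stress-responsive ankyrin repeat protein (7.40 ± 0.14, from a mean of 0.53 to 89.56 CPM), GREM1, a secreted antagonist of bone morphogenetic proteins (6.35 ± 0.20), IGFBP3, a binding protein of insulin-like growth factors (6.12 ± 0.21), and RBFOX1, a regulator of splicing (6.06 ± 0.29). SPRR2D rose by 6.60 ± 0.29, KRTAP4-9 by 6.33 ± 0.23 and KRTAP4-7 by 6.11 ± 0.24, though members of the SPRR2 and KRTAP4 families share near-identical sequence and their counts are uncertain. KRT34, KRTAP4-8 and FOXC2 went from 1, 3 and 3 counts over both DMSO libraries to 729, 1043 and 546 counts, which are ratios of 547 (95% interval 97.9 to 21600), 261 (89 to 1270) and 137 (46.5 to 664). Among the genes that fell most were TMEM119 (-6.57 ± 0.28) and the phospholipase gene PLA2G3 (-6.50 ± 0.20). They were followed by METTL7A (-4.87 ± 0.13), the argininosuccinate synthase gene ASS1 (-4.84 ± 0.20), the kinase gene MAP2K6 (-3.99 ± 0.12), the tetraspanin gene CD82 (-3.70 ± 0.18), the non-coding RNA OLMALINC (-3.64 ± 0.12), PIR (-3.64 ± 0.08) and the histone H3 gene HIST1H3J (-3.61 ± 0.08). Among these 19 genes the highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p was 3.66e-13.

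Of 21633 genes tested in A673, 12541 were called, 6828 higher and 5713 lower with SP-2509, and 4984 of them changed at least 2-fold. In the authors' deposited table, 12125 genes had an adjusted p under 0.05 for this comparison. The share of higher calls was 54.4% and became 48.7% with the stricter filter and 41.6% with upper-quartile factors, which moved the median of all genes by -0.182 log2, so fold changes under that scaling are read relative to that shift.

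Cholesterol synthesis was the list with the most uniform change in A673. Of its 25 tested members 23 fell and 1 rose, the same counts when adjusted over the list alone, with a median of -1.30. The camera adjusted p was 6.27e-32, and adjusted p = 0.0049 with an estimated correlation. INSIG1 (-2.45 ± 0.06), MVD (-2.93 ± 0.08), FDFT1 (-2.13 ± 0.06) and HMGCS1 (-2.20 ± 0.07) led the list, and PMVK rose by 0.30 ± 0.10. Members that went against their list, here and below, lie outside the naming rule and were chosen after their values were seen. Among genes known to be held down by EWSR1::FLI1, 21 of 29 rose and 4 fell (21 and 5 adjusted over the list alone, median 1.22), among them LOX (3 ± 0.07), PHLDA1 (3.97 ± 0.09) and the surface receptor gene CD44 (5.38 ± 0.15). The fibrillar collagen genes COL1A2 (-2.10 ± 0.09) and COL3A1 (-1 ± 0.09), IGFBP5 (-0.89 ± 0.13) and TGFBI (-0.46 ± 0.09) fell. The camera adjusted p was 9.53e-15, and the call was lost with adjusted p = 0.0938 with an estimated correlation. The lysosome and autophagy list had 23 of 29 members up and 4 down (the same adjusted over the list alone, median 0.85), with GPNMB at 3.36 ± 0.08 and MAP1LC3B at 1.34 ± 0.06. CTSL (-0.96 ± 0.08), WIPI1 (-1.28 ± 0.32), SQSTM1 (-0.17 ± 0.07) and ATG2A (-0.20 ± 0.08) fell. This list had a camera adjusted p of 2.73e-09, and adjusted p = 0.0938 with an estimated correlation. Of 36 histone genes 28 fell and none rose (29 adjusted over the list alone, median -1.24; camera adjusted p = 2.6e-16, and adjusted p = 0.0388 with an estimated correlation), including the linker histone genes HIST1H1D (-2.46 ± 0.06) and HIST1H1B (-2.43 ± 0.07). Many histone genes are near-identical copies, so single values are uncertain. In the same libraries small RNA genes of other kinds had a median of -0.82, with 8 of 492 higher and 111 lower.

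Targets of p53 and genes of DNA replication also moved on balance upward in A673. For p53, 15 of 22 targets rose and 3 fell (the same adjusted over the list alone), with GADD45A at 2.89 ± 0.07 and CDKN1A at 1.29 ± 0.06 (camera adjusted p = 0.000462, and adjusted p = 0.193 with an estimated correlation). RRM2B (-1.35 ± 0.09), SESN1 (-1.20 ± 0.15) and FDXR (-0.49 ± 0.09) fell. For replication, 22 of 35 rose and 7 fell (the same adjusted over the list alone), with CDC25A at 1.68 ± 0.06 and RRM2 at 1.61 ± 0.06 (camera adjusted p = 0.000462, and adjusted p = 0.465 with an estimated correlation). Among the members of complexes that hold LSD1, 11 of 19 fell and 6 rose (the same adjusted over the list alone), with RCOR2 at -2.48 ± 0.14 and HMG20B at -1.46 ± 0.09 (camera adjusted p = 0.0264, and adjusted p = 0.297 with an estimated correlation). Hypoxia genes split into 10 of 21 up and 6 down (the same adjusted over the list alone), led by KDM3A (1.82 ± 0.05) and ADM (2.64 ± 0.11), with camera adjusted p = 0.032 and adjusted p = 0.191 with an estimated correlation. ATF4 targets, genes of the integrated stress response, went both ways with 16 of 41 up and 19 down (the same adjusted over the list alone): DDIT3 (2.80 ± 0.07), ATF3 (2.66 ± 0.08) and GDF15 (3.19 ± 0.11) rose and ASNS (-2.09 ± 0.06) fell. Their median was -0.05 while camera pointed up without a call (adjusted p = 0.902). Interferon response genes (8 of 29 up, 13 down) and genes known to be activated by EWSR1::FLI1 (17 of 30 up, 9 down) had no camera call (adjusted p = 0.0936 and 0.172), and their counts were the same adjusted over the list alone. Those called with the smallest p were IFITM3 (-1.14 ± 0.07) and IFIT1 (-2.49 ± 0.18) in the first and KDSR (1.01 ± 0.06) and PPP1R1A (-1.17 ± 0.07) in the second.

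The MRPL45 knockout line responded to SP-2509 with smaller changes. The gene that rose most was GDF15, a stress-induced cytokine (1.93 ± 0.11), followed by DHRS2 (1.58 ± 0.15), TRIB3 (1.44 ± 0.07), PPP1R15A (1.43 ± 0.09), the endothelin gene EDN1 (1.43 ± 0.18) and ELAVL3 (1.39 ± 0.13). OPLAH (-1.50 ± 0.14), PIR (-1.38 ± 0.08), FAM114A1 (-1.34 ± 0.14), POU1F1 (-1.31 ± 0.11) and HIST1H3J (-1.30 ± 0.08) were among those that fell most. Of 41 ATF4 targets 19 rose and 6 fell (21 and 6 adjusted over the list alone, median 0.24; camera adjusted p = 2.09e-16, and adjusted p = 0.0548 with an estimated correlation), including DDIT3 (1.36 ± 0.08) and ATF3 (1.27 ± 0.08). Of 25 cholesterol synthesis genes 16 fell and none rose (19 adjusted over the list alone, median -0.35; camera adjusted p = 5.02e-17, and adjusted p = 0.0185 with an estimated correlation). Of 25 NRF2 targets 9 fell and none rose, among them NQO1 (-0.94 ± 0.07) and GCLM (-0.62 ± 0.06) (14 adjusted over the list alone; camera adjusted p = 1.71e-07, and adjusted p = 0.0241 with an estimated correlation). Of 21 hypoxia genes 9 rose, STC1 by 1.13 ± 0.10 and ADM by 1.09 ± 0.11 (9 adjusted over the list alone; camera adjusted p = 4.5e-07, and adjusted p = 0.0185 with an estimated correlation). In this line 4005 genes were called, 2255 higher and 1750 lower, and 301 changed at least 2-fold, with 4681 calls in the authors' deposited table. The share of higher calls, 56.3%, became 47.4% with upper-quartile factors and 68.6% without replicate 2 of its DMSO libraries. The highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p among the 11 genes named first was 3.5e-06. Without replicate 1 or replicate 2 of its SP-2509 libraries the count fell to 2615 or 2393.

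In the CYC1 knockout line the innate immune gene PTX3 rose most with SP-2509 (4.67 ± 0.21), followed by GDF15 (2.81 ± 0.14), IGFBP3 (2.77 ± 0.18), RBFOX1 (2.74 ± 0.22), the chemokine gene CXCL8 (2.63 ± 0.16) and BEX2 (2.56 ± 0.12). TMEM119 (-2.96 ± 0.16), SELENBP1 (-2.50 ± 0.18), CDK18 (-2.39 ± 0.12), TNN (-2.30 ± 0.20) and CAPN6 (-2.29 ± 0.12) were among the genes that fell most. ATF4 targets were the most uniform rising list: 37 of 41 rose and 2 fell (38 and 2 adjusted over the list alone, median 0.72), with TRIB3 at 2.47 ± 0.07, DDIT3 at 1.96 ± 0.07, ATF3 at 2.04 ± 0.08 and ATF5 at 1.84 ± 0.08. ALDH18A1 (-0.46 ± 0.07) and JDP2 (-0.28 ± 0.08) were the exceptions. The list had a camera adjusted p of 1.83e-44, and adjusted p = 0.00474 with an estimated correlation. Of 25 cholesterol synthesis genes 23 fell and none rose (24 adjusted over the list alone, median -0.94), with INSIG1 at -1.99 ± 0.07 and HMGCS1 at -1.70 ± 0.07 (camera adjusted p = 4.28e-59, and adjusted p = 0.000483 with an estimated correlation). Interferon response genes fell on balance, 13 of 29 with 3 up (the same adjusted over the list alone), with IFITM3 at -1.05 ± 0.07 and OAS3 at -0.89 ± 0.07 (camera adjusted p = 0.00116, and adjusted p = 0.219 with an estimated correlation). Those that rose include IRF7 (0.96 ± 0.16) and DDX58 (0.41 ± 0.09). In total 7217 genes were called, 4040 higher and 3177 lower, 1236 of them at least 2-fold, against 7351 calls in the authors' deposited table. Among the 11 genes named first the highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p was 2.93e-09.

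The UQCRFS1 knockout line responded with changes about as large as those of A673. SPRR2D rose by 8.06 ± 0.33, ANKRD1 by 6.10 ± 0.15, the substance P precursor gene TAC1 by 5.85 ± 0.29, KRTAP4-9 by 5.65 ± 0.24, PTX3 by 5.38 ± 0.16 and CXCL8 by 5.35 ± 0.19. PLA2G3 (-6.04 ± 0.18), ASS1 (-4.92 ± 0.18), METTL7A (-4.68 ± 0.12), the transcription factor gene CREB3L1 (-4.20 ± 0.14) and CDK18 (-4.07 ± 0.13) were among those that fell most. Of 25 cholesterol synthesis genes 24 fell and none rose (24 adjusted over the list alone, median -1.73), including INSIG1 (-3.30 ± 0.07; camera adjusted p = 1.71e-49, and adjusted p = 0.00102 with an estimated correlation). Interferon response genes fell on balance, 19 of 29 with 5 up (the same adjusted over the list alone), with IFIT1 at -4.01 ± 0.20 and OAS1 at -2.40 ± 0.16 (camera adjusted p = 0.000107, and adjusted p = 0.177 with an estimated correlation). Those that rose include USP18 (0.58 ± 0.10), IRF7 (0.72 ± 0.15), CMPK2 (0.56 ± 0.14) and DDX58 (0.33 ± 0.09). Of the genes known to be held down by EWSR1::FLI1, 18 of 29 rose and 6 fell (18 and 7 adjusted over the list alone), with PHLDA1 at 3.63 ± 0.09 and LOX at 2.42 ± 0.07 (camera adjusted p = 1.36e-09, and adjusted p = 0.177 with an estimated correlation). NRF2 targets had 14 of 25 down and 5 up (the same adjusted over the list alone), with ME1 at -1.55 ± 0.06 and AKR1C1 at -2.03 ± 0.14 (camera adjusted p = 0.00211, and adjusted p = 0.177 with an estimated correlation). FTL (0.60 ± 0.06), TXNRD1 (0.52 ± 0.05), AKR1B1 (0.73 ± 0.08), ABCC1 (0.44 ± 0.07) and SLC7A11 (0.23 ± 0.07) rose. The hypoxia list had a median of -0.26 with 10 of 21 up and 10 down (the same adjusted over the list alone), while camera pointed up without a call (adjusted p = 0.429). In total 11837 genes were called, 6404 higher and 5433 lower, 4213 of them at least 2-fold, against 11528 calls in the authors' deposited table. The share of higher calls, 54.1%, became 43.6% with upper-quartile factors, which shifted the median of all genes by -0.136. Among the 11 genes named first the highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p was 3.76e-12.

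**Figure D2:**
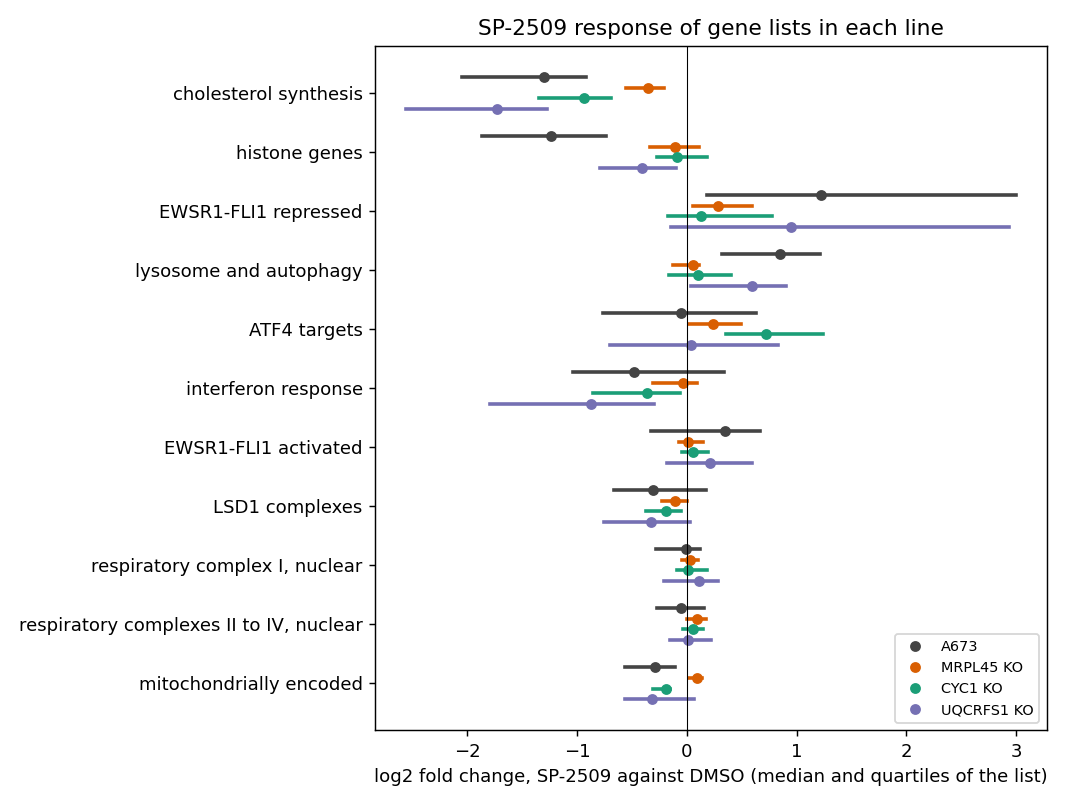
Log2 fold change with SP-2509 of the members of 11 gene lists in each of the 4 lines, with points at the median and bars from the lower to the upper quartile of the members. The cholesterol synthesis medians lie below 0 in all 4 lines, from -1.73 in the UQCRFS1 knockout line to -0.35 in the MRPL45 knockout line.

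Whether the knockout lines respond to SP-2509 as A673 does was asked with the overlap of calls and with a test of the difference. All 4 lines shared 1515 genes that rose and 974 that fell, where independent lists would share 39 and 17. Without replicate 2 of the SP-2509 libraries of the MRPL45 knockout line the sum of both was 1639. Across 10597 genes, which are not independent replicates, the fold changes of A673 correlated with those of the UQCRFS1 knockout line at r = 0.922 (slope 0.891), with the CYC1 knockout line at 0.775 (slope 0.404) and with the MRPL45 knockout line at 0.708 (slope 0.228). The size of the response was then compared on genes called in the other 2 knockout lines, so that neither line compared had chosen them. In the MRPL45 knockout line 3440 such rising genes had a median of 0.21 against 0.85 in A673 (24.8% of it), and 2513 falling genes a median of -0.23 against -0.80 (29.3%), with fry p of 1.31e-09 and 2.21e-07 for the differences. In the CYC1 knockout line the medians were 0.40 against 0.98 (41% of A673, 1982 genes) and -0.42 against -0.86 (48.3%, 1353 genes), with fry p of 9.53e-09 and 1.18e-06. In the UQCRFS1 knockout line 1609 rising genes stood at 0.93 against 1.04 (89.1%), with a fry p of 0.00265 that became 0.0815 without replicate 2 of its DMSO libraries. Its 1103 falling genes stood at -0.90 against -0.90 (99.4%, difference 0.005). There fry pointed down without a call at a p of 0.319, and the difference was -0.028 with a fry p of 0.0476 without replicate 1 of its DMSO libraries.

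**Figure D3:**
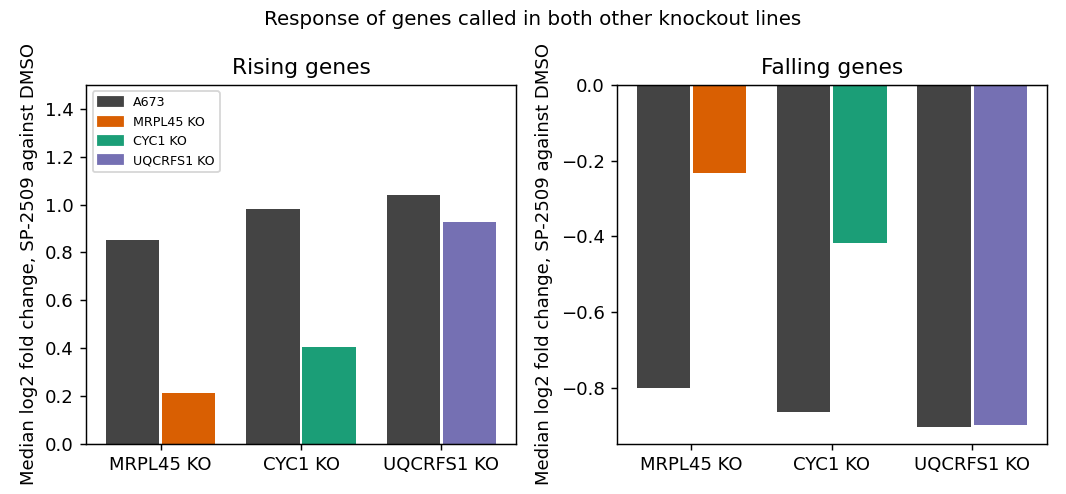
Median log2 fold change with SP-2509 in A673 and in each knockout line, drawn as bars, of the genes called in both other knockout lines, rising genes in the left panel and falling genes in the right. The rising genes reach 24.8% of the A673 median in the MRPL45 knockout line, 41% in the CYC1 knockout line and 89.1% in the UQCRFS1 knockout line.

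The largest differences in response between the MRPL45 knockout line and A673 were opposite in sign to the response of A673. The responses of these genes inside the knockout line are not given here, so a smaller response is not told from none. TMEM119 (5.89 ± 0.36), PLA2G3 (4.77 ± 0.58), METTL7A (4.18 ± 0.16), MAP2K6 (3.89 ± 0.16) and CD82 (3.62 ± 0.23), all of which fell in A673, had positive differences. ANKRD1 (-6.37 ± 0.17), GREM1 (-5.98 ± 0.24) and IGFBP3 (-5.46 ± 0.26), all of which rose in A673, had negative ones. KRT34 (-7.30 ± 0.54), the zinc finger gene ZNF90 (-7.23 ± 0.97) and FOXC2 (-5.82 ± 0.52) had 1, 0 and 3 counts in A673 with DMSO, so their fitted values depend on the prior count and are no bounds. Cholesterol synthesis genes differed with 22 of 25 positive and 1 negative (23 and 1 adjusted over the list alone, median 0.98; camera adjusted p = 1.07e-29, and adjusted p = 0.00884 with an estimated correlation). Lysosome and autophagy genes differed with 19 of 29 negative and 1 positive (20 and 2 adjusted over the list alone, median -0.79; camera adjusted p = 1.84e-13, and adjusted p = 0.0357 with an estimated correlation), led by GPNMB (-3.30 ± 0.11). The exceptions were PMVK (-0.53 ± 0.14) and CTSL (0.73 ± 0.11). In all, 8368 genes differed, 3137 with a positive and 5231 with a negative difference. The positive share of 37.5% became 52.9% with upper-quartile factors, which shifted the median of all genes by 0.152. The highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p among these 11 genes was 2.5e-06.

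Between the CYC1 knockout line and A673 the positive differences were led by ASS1 (4.61 ± 0.25), CHAC1 (3.88 ± 0.16), PCK2 (3.49 ± 0.16) and the asparagine synthetase gene ASNS (3.33 ± 0.09), with TMEM119 at 3.61 ± 0.38 and the sulfotransferase gene SULT1E1 at 3.58 ± 0.26. Negative differences were largest for KRTAP4-8 (-6.17 ± 0.44), GREM1 (-5.64 ± 0.34), HKDC1 (-5.61 ± 0.31), ANKRD1 (-5.59 ± 0.18), FOXC2 (-4.55 ± 0.67) and the Wnt antagonist gene DKK1 (-4.46 ± 0.22), of which KRTAP4-8 and FOXC2 again rest on 3 counts in A673 with DMSO and give no bound. Of 41 ATF4 targets 28 had a positive and 6 a negative difference (30 and 6 adjusted over the list alone, median 0.67; camera adjusted p = 8.6e-24, and adjusted p = 0.0294 with an estimated correlation). Of 29 genes known to be held down by EWSR1::FLI1, 22 had a negative and 4 a positive difference (the same adjusted over the list alone, median -0.71; camera adjusted p = 1.98e-20, and adjusted p = 0.0294 with an estimated correlation), with CTGF at -3.50 ± 0.12 and THBS1 at -3.89 ± 0.14. The positive members were COL1A2 (1.38 ± 0.13), TGFBI (1 ± 0.14), IGFBP5 (1.02 ± 0.23) and COL3A1 (0.35 ± 0.13). In all, 7325 genes differed, 2772 positive and 4553 negative. The positive share of 37.8% became 57% with upper-quartile factors, which shifted the median of all genes by 0.151. The highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p among these 12 genes was 9.97e-06.

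Between the UQCRFS1 knockout line and A673 fewer genes differed. The histone genes HIST1H3J (2.07 ± 0.10), HIST1H1D (1.88 ± 0.08) and HIST1H1B (1.71 ± 0.10), the neuropeptide gene TAC1 (2.14 ± 0.45), the immediate early gene EGR1 (1.84 ± 0.23) and PTPRO (1.63 ± 0.31) had the largest positive differences. The haem oxygenase gene HMOX1 (-2.71 ± 0.20), the receptor kinase gene AXL (-2.38 ± 0.25), the autophagy receptor gene OPTN (-1.94 ± 0.14), MGLL (-1.93 ± 0.23) and SDC1 (-1.79 ± 0.32) had negative ones, as had FOXC2 (-3.22 ± 0.74). FOXC2 had 3 counts in A673 with DMSO, and its call was lost without replicate 2 of the DMSO libraries of the knockout line (-2.52, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.114). Interferon response genes had 13 of 29 negative and none positive differences (15 adjusted over the list alone, median -0.54; camera adjusted p = 1.83e-08, and adjusted p = 0.0454 with an estimated correlation), led by IFIT2 (-2.83 ± 0.27). Histone genes had only positive calls, 18 of 36 here (20 adjusted over the list alone), 23 in the MRPL45 comparison (24) and 24 in the CYC1 comparison (26), with medians of 0.95, 1.12 and 1.23 and camera adjusted p of 1.89e-52, 1.7e-17 and 7.3e-32 (adjusted p = 0.00135, 0.0292 and 0.00835 with an estimated correlation). The 492 small RNA genes of other kinds had medians of 0.59, 0.59 and 0.57 in the same 3 differences, with 23, 41 and 23 higher and 0, 2 and 1 lower. The 3 differences share the A673 libraries, and with them any chance value of those libraries. In all, 2315 genes differed, 654 positive and 1661 negative, and 1313 without replicate 1 of the A673 SP-2509 libraries. The positive share of 28.3% became 40.2% with upper-quartile factors. Apart from FOXC2, the highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p among these 12 genes was 0.00262.

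The knockout lines were also compared with A673 under DMSO, which asks how the clones differ before treatment. A knockout is carried by 1 clone each, so a difference between line and A673 cannot be assigned to the knockout rather than to the clone. In the MRPL45 knockout line the nucleoside transporter gene SLC28A3 went from 0 counts in A673 to 8258 and ZDHHC15 from 0 to 1060, at least 3010-fold and at least 387-fold higher with a floor of 3 counts over the group. ZNF354C, ZNF667, GRIK3 and BRINP1 had 1 or 2 counts in A673 and were higher by ratios of 1350 (95% interval 374 to 11200), 1300 (234 to 51600), 1130 (313 to 9360) and 631 (113 to 25000). The N-cadherin gene CDH2 (-7.81 ± 0.13), the protease gene TLL1 (-7.31 ± 0.16) and the chromatin organiser gene SATB1 (-7.19 ± 0.26) were lower. ZNF385D was at least 193-fold lower, with 633 counts in A673 and 0 in the knockout line, and MGST1 and FIGN were lower by ratios of 1740 (482 to 14400) and 1580 (284 to 62500). The highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p among these 12 genes was 1.15e-12.

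Genes known to be held down by EWSR1::FLI1 were higher in the MRPL45 knockout line, 24 of 29 with 2 lower (the same adjusted over the list alone, median 1.72), among them CD44 (7.70 ± 0.13, from a mean of 0.46 to 95.95 CPM) and CTGF (3.74 ± 0.09). DKK1 (-1.60 ± 0.30) and CDH11 (-0.24 ± 0.06) were lower. The camera adjusted p was 1.16e-31, and adjusted p = 0.0241 with an estimated correlation. Of 75 mitochondrial ribosomal protein genes 54 were lower and 3 higher (the same adjusted over the list alone, median -0.48), with MRPS23 at -1.35 ± 0.07 and MRPS7 at -1.18 ± 0.07 (camera adjusted p = 2.03e-07, and adjusted p = 0.4 with an estimated correlation). The higher members were MRPS6 (0.40 ± 0.09), MRPL22 (0.31 ± 0.08) and MRPS30 (0.13 ± 0.05). This list was not checked against the shifts by chromosome given below. Of 35 DNA replication genes 28 were lower and 1 higher (29 and 1 adjusted over the list alone), with PRIM1 at -1.62 ± 0.08 and RRM2 at 0.28 ± 0.06 (camera adjusted p = 6.42e-08, and adjusted p = 0.352 with an estimated correlation). Histone genes were lower in 29 of 36 cases with 1 higher, HIST1H1PS1 at 1.10 ± 0.42 (the same adjusted over the list alone, median -1.56; camera adjusted p = 9.32e-21, and adjusted p = 0.0241 with an estimated correlation). Cholesterol synthesis genes were lower in 23 of 25 with none higher (24 adjusted over the list alone, median -0.72; camera adjusted p = 2.54e-11, and adjusted p = 0.0447 with an estimated correlation). Hypoxia genes were higher in 13 of 21 cases with 2 lower (13 and 3 adjusted over the list alone), with AK4 at 4.21 ± 0.12 and NDRG1 at 3.91 ± 0.14 (camera adjusted p = 0.000392, and adjusted p = 0.0447 with an estimated correlation). JMJD6 (-1.35 ± 0.08) and VEGFA (-0.70 ± 0.06) were lower. Lysosome and autophagy genes were higher in 21 of 29 cases with 4 lower (the same adjusted over the list alone; camera adjusted p = 7.57e-06, and adjusted p = 0.199 with an estimated correlation), the lower members including UVRAG (-0.71 ± 0.08), FNIP2 (-0.52 ± 0.07) and ULK1 (-0.43 ± 0.07). Mesenchymal differentiation genes were higher in 11 of 16 with 3 lower (12 and 3 adjusted over the list alone), with ZEB1 at 4.78 ± 0.20 (camera adjusted p = 0.00772, and adjusted p = 0.11 with an estimated correlation). SOX9 (-0.24 ± 0.06), MYH3 (-0.65 ± 0.20) and COL2A1 (-0.69 ± 0.23) were lower. In total 12513 genes were called, 6249 higher and 6264 lower, 5139 of them at least 2-fold, against 12098 calls in the authors' deposited table.

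In the CYC1 knockout line with DMSO the growth factor gene TGFA (6.11 ± 0.29), the transcription factor gene DMRTA2 (6.07 ± 0.24), EPAS1, which encodes a hypoxia-inducible factor (5.74 ± 0.10, from 0.9 to 47.96 CPM), LRRC32 (5.37 ± 0.22) and the small heat shock protein gene CRYAB (4.8 ± 0.20) were higher than in A673. So was MBD3L3 (4.88 ± 0.75), a member of a multicopy family whose counts are uncertain. ARRDC4 (-4.47 ± 0.11), PTGFRN (-4.41 ± 0.12), STON2 (-4.23 ± 0.16), GPHN (-4.06 ± 0.17) and the Notch ligand gene JAG2 (-3.84 ± 0.16) were among the genes that were lower. Interferon response genes were higher, 19 of 29 with 1 lower (20 and 2 adjusted over the list alone, median 0.58), with SAMD9 at 1.72 ± 0.11, CMPK2 at 1.91 ± 0.14 and the lower IFI27 at -1.39 ± 0.46 (camera adjusted p = 8.44e-05, and adjusted p = 0.116 with an estimated correlation). So were genes of MHC class I presentation, 11 of 14 with none lower (11 and 1 adjusted over the list alone), with HLA-C at 0.87 ± 0.07 and TAP1 at 1.38 ± 0.17 (camera adjusted p = 0.000181, and adjusted p = 0.116 with an estimated correlation). Genes known to be activated by EWSR1::FLI1 were higher in 16 of 30 cases and lower in 7 (17 and 7 adjusted over the list alone), with SOX6 at 1.07 ± 0.06 and NKX2-2 at 0.84 ± 0.07 (camera adjusted p = 0.00471, and adjusted p = 0.118 with an estimated correlation). Genes known to be held down by EWSR1::FLI1 were higher in 17 of 29 cases and lower in 5 (18 and 5 adjusted over the list alone, median 0.33), with CTGF at 2.95 ± 0.09 and PHLDA1 at 2.10 ± 0.10 (camera adjusted p = 1.09e-05, and adjusted p = 0.237 with an estimated correlation). The lower members were TNC, IGFBP5 (-2.48 ± 0.16), TGFBI (-0.90 ± 0.10), CDH11 (-0.44 ± 0.06) and COL1A2 (-0.23 ± 0.09). ATF4 targets were lower, 31 of 41 with 4 higher (31 and 5 adjusted over the list alone, median -0.51), with ASNS at -1.75 ± 0.06 and PCK2 at -2.39 ± 0.11 (camera adjusted p = 2.14e-20, and adjusted p = 0.113 with an estimated correlation). ALDH1L2 (1.41 ± 0.12), SLC38A2 (0.43 ± 0.06), PPP1R15A (0.57 ± 0.09) and JDP2 (0.34 ± 0.09) were higher. Cholesterol synthesis genes were lower in 16 of 25 cases with none higher (17 adjusted over the list alone), with INSIG1 at -1.04 ± 0.06 (camera adjusted p = 4.48e-09, and adjusted p = 0.116 with an estimated correlation). In total 8137 genes were called, 4630 higher and 3507 lower, 2219 of them at least 2-fold, against 8026 calls in the authors' deposited table. The share of higher calls, 56.9%, became 43.4% with upper-quartile factors. The highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p among the 11 genes named first was that of MBD3L3, 0.000818.

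In the UQCRFS1 knockout line with DMSO the glycoprotein gene PDPN (3.75 ± 0.19), the sestrin gene SESN3 (3.21 ± 0.17), the lipid transporter gene ABCG1 (3.13 ± 0.25), ZNF85 (3 ± 0.11), DZIP1 (2.61 ± 0.16) and the proteoglycan gene DCN (2.56 ± 0.19) were higher than in A673. The amino acid transporter gene SLC38A5 (-6.40 ± 0.13, from 36.3 to 0.43 CPM) and the solute carrier gene SLC43A3 (-5.35 ± 0.21) were lower. So were the phosphodiesterase gene PDE10A (-4.90 ± 0.14), the matrix metalloproteinase genes MMP1 (-4.25 ± 0.14) and MMP16 (-3.61 ± 0.20), and NPR3 (-3.41 ± 0.10). Genes known to be held down by EWSR1::FLI1 were lower in this line, 16 of 29 with 3 higher (16 and 4 adjusted over the list alone, median -0.39), with TNC, SPARC (-0.50 ± 0.06) and CDKN1A (-0.44 ± 0.07) among them (camera adjusted p = 0.000545, and adjusted p = 0.609 with an estimated correlation). COL1A2 (0.62 ± 0.09), LOX (0.30 ± 0.07) and ANXA1 (0.28 ± 0.08) were higher. Genes of MHC class I presentation were lower in 8 of 14 cases with 2 higher (the same adjusted over the list alone), with ERAP1 at -0.96 ± 0.07 and PSMB8 at -2.34 ± 0.29 (camera adjusted p = 0.013, and adjusted p = 0.416 with an estimated correlation). HLA-C (0.30 ± 0.07) and B2M (0.21 ± 0.07) were higher. ATF4 targets were lower in 27 of 41 cases with 4 higher (28 and 4 adjusted over the list alone, median -0.28), with the tRNA synthetase genes AARS (-0.62 ± 0.06), SARS (-0.59 ± 0.06) and EPRS (-0.50 ± 0.06) among them (camera adjusted p = 3.84e-07, and adjusted p = 0.416 with an estimated correlation). Those higher include ALDH1L2 (0.62 ± 0.12), CEBPG (0.21 ± 0.06) and SLC38A2 (0.15 ± 0.06). The MRPL45 knockout line had 27 of 41 ATF4 targets lower and 11 higher as well (the same adjusted over the list alone, median -0.51; camera adjusted p = 0.00125, and adjusted p = 0.394 with an estimated correlation), ATF4 itself at -1.53 ± 0.06. In total 6658 genes were called, 3417 higher and 3241 lower, 1124 of them at least 2-fold, against 6868 calls in the authors' deposited table. The highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p among the 12 genes named first was 1.21e-09.

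The calls of the 3 knockout lines against A673 overlapped in the same and in opposite directions. The MRPL45 and CYC1 knockout lines shared 2338 higher and 1667 lower genes, where independent lists would share 1337 and 1015. For the MRPL45 and UQCRFS1 knockout lines the counts were 1393 and 1308 (987 and 938 if independent), and for the CYC1 and UQCRFS1 knockout lines 1144 and 935 (731 and 525). In opposite directions, 826 genes were higher in the MRPL45 and lower in the CYC1 knockout line, and 1238 the reverse (1013 and 1341 if independent). These counts were 1098 and 1162 (936 and 989) for the MRPL45 and UQCRFS1 knockout lines, and 909 and 691 (694 and 554) for the CYC1 and UQCRFS1 knockout lines. So only the first pair shared fewer opposite calls than independent lists would, and in the other pairs the excess held in both directions. All 3 shared 665 higher and 456 lower genes (211 and 152). Unchanged groups simulated against the same controls shared 0 calls in 10 draws. Groups without a changed gene hold few or no calls by construction. So this count cannot show how much the shared controls add to the overlap of changed genes. Across 10597 genes, which are not independent replicates, the fold changes correlated at r = 0.309, 0.02 and 0.05 for these pairs, against 0.503, 0.517 and 0.511 in the simulation. With no changed gene, the simulated r follows from the shared controls alone. It is therefore no measure of how alike the real lines are. The covariances were 0.156, 0.0077 and 0.0111 against 0.0061, 0.0063 and 0.0062, which leaves 0.15, 0.0014 and 0.0049. The 2 control libraries were not split between the comparisons, so part of the excess may come from the shared controls.

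Genes of the respiratory chain were followed in all lines, since the knockouts concern it. With all libraries the nuclear genes of complex I and of complexes II to IV had no camera call with SP-2509 in any line. No knockout line against A673 with DMSO had one either. Both lists were called in the difference in response of the UQCRFS1 knockout line, but lost the call without single libraries. They also lost it with an estimated correlation and the replicate block (camera adjusted p = 0.571 and 0.643). With DESeq2 size factors both medians there were 0.048, with 2 members each positive and none negative. For complexes II to IV with SP-2509 in the MRPL45 knockout line the camera adjusted p of 0.117 became 0.000375 without replicate 2 of its DMSO libraries and 0.0381 without replicate 1 of its SP-2509 libraries. Of 37 complex I genes, 14 were lower and 6 higher in the MRPL45 knockout line with DMSO (the same adjusted over the list alone, camera adjusted p = 0.226), with NDUFAB1 at -0.91 ± 0.07. Of 26 genes of complexes II to IV, 13 were lower and 3 higher there (the same adjusted over the list alone), with SDHD at -1.18 ± 0.08. SDHA (0.46 ± 0.07), COX5A (0.35 ± 0.08) and COX7A2L (0.23 ± 0.07) were the higher ones. Their camera adjusted p of 0.0586 became 0.0262 without replicate 2 of the A673 DMSO libraries and 0.00594 without replicate 2 of the DMSO libraries of the knockout line. In the CYC1 knockout line the complex III gene UQCRC2 was lower (-0.43 ± 0.07), as it was in the UQCRFS1 knockout line (-0.51 ± 0.07). Neither value was corrected for the shifts by chromosome given below. ATP synthase genes fell with SP-2509 in A673, 8 of 18 with none up (7 adjusted over the list alone), with ATP5G1 at -1.14 ± 0.08 and ATP5H at -0.90 ± 0.08 (camera adjusted p = 0.0252, and adjusted p = 0.443 with an estimated correlation). With DMSO 10 of 18 were lower and none higher in the MRPL45 knockout line than in A673 (10 adjusted over the list alone, median -0.33), with ATP5G3 at -0.81 ± 0.07 and ATP5G1 at -0.87 ± 0.08. The camera adjusted p there was 0.0405, and adjusted p = 0.45 with an estimated correlation, and 0.0571 without replicate 1 of its DMSO libraries. In the differences in response, 9 of 18 were positive for the MRPL45, 7 for the CYC1 and 1, ATP5G1 (0.62 ± 0.11), for the UQCRFS1 knockout line. None was negative, and the counts were the same adjusted over the list alone. The camera adjusted p were 0.00237, 0.00606 and 0.0027, with medians of 0.41, 0.26 and 0.20, and all 3 calls were lost with an estimated correlation (adjusted p = 0.422, 0.386 and 0.318). Of the 13 genes encoded by the mitochondrial genome, MT-ND2 (1.96 ± 0.28), MT-ND1 (2.09 ± 0.31) and MT-ND3 (1.53 ± 0.38) were higher in the MRPL45 knockout line with DMSO, also adjusted over the list alone. The list had no call there, with a camera adjusted p of 0.156 that became 0.0202 without replicate 1 of the A673 DMSO libraries and 0.00181 without replicate 2 of the knockout DMSO libraries.

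Markers of leukocytes, epithelium, endothelium, and of melanocytes and liver were followed as signs of other cell types. None of these 4 lists had a camera call with all libraries in the 10 comparisons of the design, which leave out the knockout lines against A673 under SP-2509. Single markers moved with the line: KRT8 was higher in the MRPL45 knockout line (2.39 ± 0.11) and the CYC1 knockout line (2.71 ± 0.11) with DMSO, and the melanocyte genes MITF (3.05 ± 0.23) and TYRP1 (2.94 ± 0.23) and the leukocyte gene LCP1 (1.61 ± 0.06) were higher in the MRPL45 knockout line. TYRP1 rose with SP-2509 in A673 (3.32 ± 0.22). With DESeq2 size factors 4 of 5 melanocyte and liver members were higher and none lower in the MRPL45 knockout line with DMSO (median 2.965). The same counts held with SP-2509 in A673 (1.935) and in the UQCRFS1 knockout line (0.909). Against A673 with DMSO, 1 member was higher in the CYC1 and 1 lower in the UQCRFS1 knockout line. Of 6 epithelial members 3 were higher and 1 lower in the MRPL45 knockout line with DMSO (median 1.725). The melanocyte and liver list was called in the MRPL45 knockout line, where its camera adjusted p was 0.0586, without replicate 1 of the A673 DMSO libraries (0.035) and without replicate 1 or 2 of its own DMSO libraries (0.0495 and 0.0493). It was called in A673 with SP-2509 (0.0882 with all libraries) without replicate 1 or 2 of the SP-2509 libraries (0.0371 and 0.0431). The epithelial list was called in the MRPL45 knockout line (0.0586 with all libraries) without replicate 1 of its DMSO libraries (0.0329) and in the CYC1 knockout line (0.0844 with all libraries) without replicate 2 of its DMSO libraries (0.0447).

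Expression in the knockout lines was shifted by chromosome relative to A673. Over 9726 protein-coding genes of the 22 autosomes, the median log2 fold change against A673 with DMSO was -0.46 on chromosome 4 and -0.37 on chromosome 17 in the MRPL45 knockout line, and 0.39 on chromosomes 10 and 14. In the CYC1 knockout line it was -0.39 on chromosome 14 and -0.34 on chromosome 13. In the UQCRFS1 knockout line it was -0.36 on chromosome 5 and 0.40 on chromosome 19. On chromosome 16 it was -0.25, -0.23 and -0.27 in the MRPL45, CYC1 and UQCRFS1 knockout lines. The SD of the 22 medians was 0.24, 0.156 and 0.154 in the MRPL45, CYC1 and UQCRFS1 knockout lines, against at most 0.072, 0.032 and 0.034 in 1000 shuffles of the genes. The medians against A673 with SP-2509, which come from other libraries, correlated with those with DMSO at r = 0.988, 0.942 and 0.973. CDH2, SATB1, the other genes named above and the gene lists were not corrected for these shifts.

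**Figure D4:**
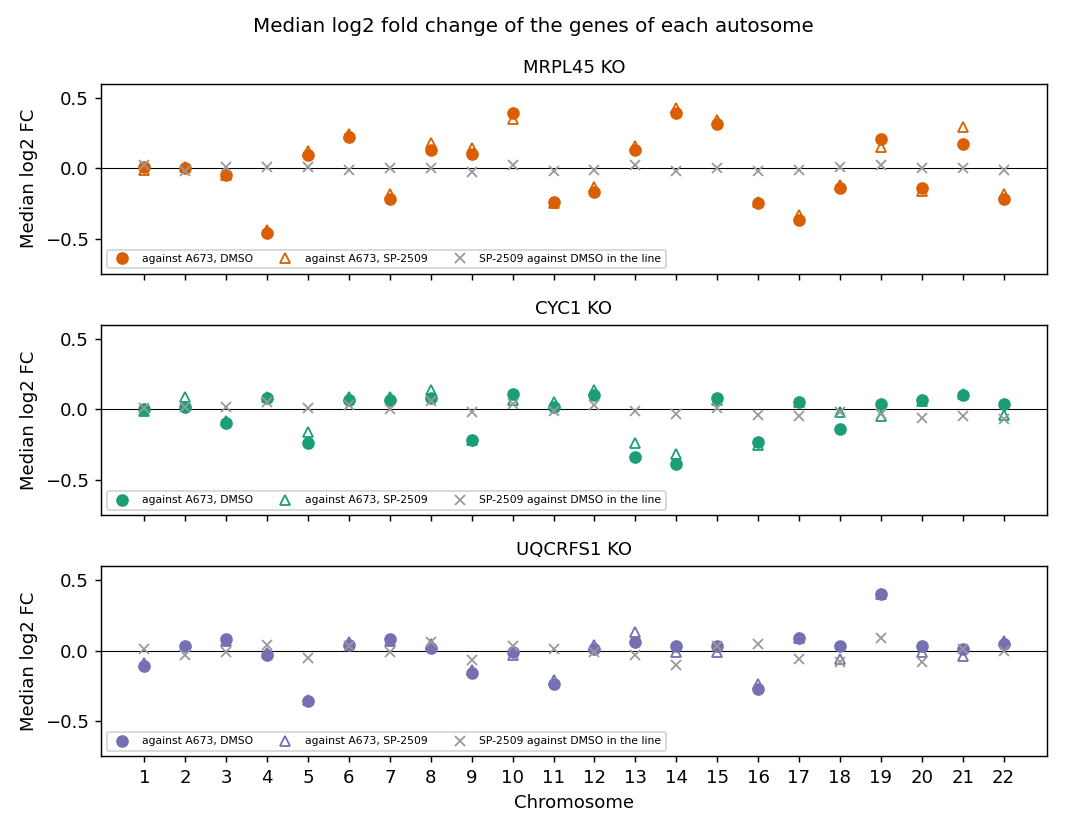
Median log2 fold change of protein-coding genes on each of the 22 autosomes (horizontal axis), in a panel for each knockout line: against A673 with DMSO (dots), against A673 with SP-2509 (triangles), and with SP-2509 inside the line (crosses). Dots and triangles lie close together, with chromosome 4 at -0.46 in the MRPL45 knockout line, chromosome 14 at -0.39 in the CYC1 knockout line and chromosome 19 at 0.40 in the UQCRFS1 knockout line.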

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

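The tests of small RNA carry-over and of copy number were chosen only after the result was seen. Differences in response to SP-2509 between a knockout line and A673 were tested with an interaction term, and those that passed are given here with their values. It called 8368 genes for the MRPL45, 7325 for the CYC1 and 2315 for the UQCRFS1 knockout line. Median differences of lists that also passed with an estimated correlation, in the fit without a replicate block, were, for the MRPL45 knockout line, 0.976 (cholesterol synthesis), -0.788 (lysosome and autophagy) and 1.122 (histone genes). For the CYC1 knockout line they were -0.707 (genes held down by EWSR1::FLI1), 0.669 (ATF4 targets), -0.702 (lysosome and autophagy) and 1.229 (histone genes). For the UQCRFS1 knockout line they were -0.28 (cholesterol synthesis), -0.252 (hypoxia), -0.537 (interferon response), -0.331 (lysosome and autophagy) and 0.945 (histone genes). With the block added, only cholesterol synthesis in the MRPL45 knockout line and the histone genes kept their call, as given below. Single genes differed in the MRPL45 knockout line by 5.89 (TMEM119), 4.77 (PLA2G3), 4.18 (METTL7A), 3.89 (MAP2K6), 3.62 (CD82), -7.3 (KRT34), -7.23 (ZNF90), -6.37 (ANKRD1), -5.98 (GREM1), -5.82 (FOXC2) and -5.46 (IGFBP3). In the CYC1 knockout line they differed by 4.61 (ASS1), 3.88 (CHAC1), 3.61 (TMEM119), 3.58 (SULT1E1), 3.49 (PCK2), 3.33 (ASNS), -6.17 (KRTAP4-8), -5.64 (GREM1), -5.61 (HKDC1), -5.59 (ANKRD1), -4.55 (FOXC2) and -4.46 (DKK1). In the UQCRFS1 knockout line the values were 2.14 (TAC1), 2.07 (HIST1H3J), 1.88 (HIST1H1D), 1.84 (EGR1), 1.71 (HIST1H1B), 1.63 (PTPRO), -3.22 (FOXC2), -2.71 (HMOX1), -2.38 (AXL), -1.94 (OPTN), -1.93 (MGLL) and -1.79 (SDC1). The values of KRT34, ZNF90, FOXC2 and KRTAP4-8 rest on 0 to 3 counts in A673 with DMSO and are no bounds. The 3 sets of differences share the A673 libraries. Without replicate 2 of the DMSO libraries of the UQCRFS1 knockout line, the difference of FOXC2 there lost its call, and without replicate 1 of the A673 SP-2509 libraries the count of that line was 1313.

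The MRPL45 knockout line responded less to SP-2509 than A673. With all libraries thinned to the smallest total, A673 still had 3.03 times as many called genes, above the bound of 1.5 that a depth effect would need. A wider spread between replicates would leave fold changes in place, but genes called in both other knockout lines moved by 26.3% of A673 (26.6% to 27.4% with 1 library left out), below the bound of 67%. Of the genes called by SP-2509 in the UQCRFS1 knockout line, 3098 stood within 0.25 log2 of A673 before treatment in the MRPL45 knockout line. These responded at 25.8% of A673 (25.7% to 28.3% with 1 library left out), below the bound of 67%. They were picked for a start near A673, so a start near the SP-2509 level was set aside by the choice, not tested in them. Their weak response shows that a start of each gene near its SP-2509 level is not needed for a smaller response. This covers 3098 of 11837 called genes and does not speak for the others. A prior state that dampens all genes alike would give the same values and is not excluded. The 5343 genes that already stood over 0.25 log2 in the SP-2509 direction responded at 20.2%, and the 3396 away from it at 33.2%. Their median shifts in that direction before treatment were 0.829 and -0.628 log2, against median responses of 0.964 and 0.515 in A673. Whether such a start adds a part stays open, since this split uses DMSO libraries that also enter both responses. An effect of the knockout or of its clone stays open and was not tested.

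Histone transcripts were lower with SP-2509 in A673. Reads shared between near-identical copies would leave their sum in place, but the log2 ratio of their summed CPM was -1.24, and -1.12 from the lowest DMSO to the highest SP-2509 library. Less carry-over of RNA without a poly(A) tail is a candidate explanation, since small RNA genes of other kinds had a median of -0.82 in the same comparison. In the MRPL45 knockout line with DMSO the histone median was -1.557 while that of the small RNA genes was -0.062. An effect of SP-2509 on histone genes stays open and was not tested.

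Expression was shifted by chromosome in the knockout lines relative to A673. Removing the trend with GC content kept at least 98.5% of the SD of the chromosome medians with DMSO and at least 97.2% with SP-2509. The state of the shared A673 DMSO libraries would not carry over to other libraries, but the medians against A673 with SP-2509 correlated at 0.94 or more with those with DMSO. Copy number differences between the lines are a candidate explanation, since the SP-2509 response inside a line had at most 0.33 of the SD of the line against A673. Any other stable difference between the lines would cancel inside a line too, so this ratio does not single out copy number. With DMSO the median of chromosome 16 was -0.25, -0.23 and -0.27 in the MRPL45, CYC1 and UQCRFS1 knockout lines. The CYC1 and UQCRFS1 knockout lines were both lower on chromosome 5 (-0.24 and -0.36), and the MRPL45 knockout line was not (0.09). A shift shared by all knockout lines can also lie in the A673 cells they are compared with. No DNA was measured. Whether such differences come from the clone, from the knockout or from the A673 cells was not tested.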

How the results depend on the processing

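The thinned libraries and the estimated correlation combined with the replicate block were chosen after seeing the data. The counts of called genes stayed within 1.5 times of those reported with other scalings, filters, the test of DESeq2, fits to the libraries compared and the replicate number as a replicate block. With the replicate block they were 13179, 4888, 7968 and 12466 for SP-2509 in A673 and in the MRPL45, CYC1 and UQCRFS1 knockout lines, 13091, 8896 and 7542 for these knockout lines against A673, and 9132, 8087 and 3018 for the differences in response. A threshold of 2-fold lowers counts by construction, to 4984, 301, 1236 and 4213, to 5139, 2219 and 1124, and to 2712, 1955 and 395 in the same order, and the genes shared by all 4 lines to 111. Thinned libraries gave 11156, 3677, 6442 and 10516 for SP-2509. Libraries with the same replicate number share only a number per the labels. Yet residuals correlated over 0.1 in 28 of 28 pairs of groups (0.125 to 0.651, median 0.492), which hints at a shared step. That 16 of 16 libraries correlated best with their own number follows from this with 2 libraries per group and adds no evidence. Of 230 list results, 167 kept their call or lack of it with an estimated correlation and 63 lost it, which left 24 calls over all lists (13 combined with the block, 135 with the block alone, 128 as reported). The 11 calls lost only when combined with the block (adjusted p by camera) were, in the MRPL45 knockout line, NRF2 targets with SP-2509 (0.0786) and cholesterol synthesis and hypoxia against A673 with DMSO (both 0.0894). The other 8 were differences in response: lysosome and autophagy in the MRPL45 knockout line (0.087), and genes held down by EWSR1::FLI1, ATF4 targets and lysosome and autophagy in the CYC1 knockout line (0.058, 0.058 and 0.0814). The rest were cholesterol synthesis, hypoxia, interferon response and lysosome and autophagy in the UQCRFS1 knockout line (0.0854, 0.0967, 0.0854 and 0.0854). Of 1075 results for genes taken by the naming rule, 1064 were the same with DESeq2 size factors, 1049 with upper-quartile factors, 1060 without a filter and 1055 with the block, as were 1014 of 1031 with the stricter filter, 1026 of 1057 with only the libraries compared and 1025 of 1048 with DESeq2. The exception in direction was KDM1A with SP-2509 in the UQCRFS1 knockout line, -0.12 with upper-quartile factors, which shifted the median of all genes there by -0.136. The share of higher calls against A673 went from 49.9% to 55.5% with upper-quartile factors in the MRPL45 and from 51.3% to 49.4% with DESeq2 size factors in the UQCRFS1 knockout line. With 1 library left out, the lone library is assumed to vary like the other groups. Such fits kept 5303 of 5568 gene results and 1137 of 1196 list results. Their counts for SP-2509 ranged from 10885 to 11561 in A673, 2393 to 3093 in the MRPL45, 5151 to 5700 in the CYC1 and 10306 to 10748 in the UQCRFS1 knockout line. For the knockout lines against A673 they ranged from 11252 to 11969, 6192 to 6899 and 4973 to 5539, for the differences from 7061 to 8023, 5872 to 6856 and 1313 to 2212, and for the genes shared by all 4 lines from 1639 to 2530 (2489 as reported). The difference of the shared response ranged from -0.648 to -0.595 (rising) and 0.561 to 0.619 (falling) in the MRPL45 and from -0.617 to -0.535 and 0.44 to 0.504 in the CYC1 knockout line. In the UQCRFS1 knockout line it ranged from -0.14 to -0.059 for rising genes, where the call was lost without replicate 2 of its DMSO libraries, and from -0.028 to 0.05 for falling genes. For genes changed at least 2-fold in the other lines, the differences grew from -0.639 to -1.996 (rising) and from 0.565 to 1.525 (falling) in the MRPL45 and from -0.579 to -1.375 and 0.447 to 1.226 in the CYC1 knockout line. For the UQCRFS1 knockout line the rising difference was -0.305 and the falling -0.326, opposite in sign to the reported 0.005, both without a call (fry p of 0.992 and 0.835). The camera adjusted p of the mitochondrially encoded list with SP-2509 in the MRPL45 knockout line ranged from 6.23e-05 to 0.859, and its direction turned without replicate 2 of the DMSO libraries (0.0301). Apart from the threshold and the smaller number of libraries, the cause was not tested.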

Other observations

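The tests of the knockout lines against A673 under SP-2509 were all chosen after seeing the data. With SP-2509 in both, 12833 genes were called in the MRPL45, 10293 in the CYC1 and 8253 in the UQCRFS1 knockout line. The ATF4 targets, which had medians of -0.505, -0.511 and -0.277 in the 3 lines against A673 with DMSO, had medians of -0.178, 0.073 and -0.024 against A673 with SP-2509, with no call (camera adjusted p of 0.457, 0.32 and 0.872). The 3 medians with DMSO share the A673 DMSO libraries. Histone genes had medians of -0.444, 1.215 and 1.051 against A673 with SP-2509, with camera adjusted p of 0.0359, 1.68e-25 and 6.56e-31, and adjusted p = 0.627, 0.0164 and 0.0088 with an estimated correlation. Of the 36 histone genes, 29 were higher and none lower in the CYC1 and 20 higher and none lower in the UQCRFS1 knockout line. Of the marker lists of other cell types, leukocyte markers were called in the MRPL45 (median 1.113, camera adjusted p = 0.0482) and endothelial markers in the CYC1 knockout line (median 0.295, camera adjusted p = 0.0378). Both calls were lost with an estimated correlation (adjusted p = 0.268 and 0.294). Of 37 complex I genes 14 were higher and 6 lower in the UQCRFS1 knockout line (median 0.231, camera adjusted p = 0.00693). That call was also lost with an estimated correlation (adjusted p = 0.492).

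The authors' deposited tables also set each knockout line with SP-2509 against A673 with DMSO, a comparison that changes line and treatment together. They list 12589, 10072 and 11863 genes with an adjusted p under 0.05 for the MRPL45, CYC1 and UQCRFS1 knockout lines.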
